A study of Mus musculus with 4 samples.

How the data were processed

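RNA-seq of mouse embryonic stem cells was analysed in 4 libraries. Per the labels, 2 came from wild-type cells and 2 from a Kdm2a knockout line. The titles and the treatment protocol speak of a knockout, but the genotype label of these samples speaks of a knock-down, and nothing in the labels settles which holds. Cells were grown in serum medium with LIF on gelatin. The knockout line was made by transfecting a guide RNA and expanding a single clone after sorting for GFP. Libraries were built from total RNA with a BGISEQ kit by random-primed cDNA synthesis.

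The authors deposited a table of whole-number read counts per gene, with no normalization. Per the submitters' processing notes, HISAT2, featureCounts and the mm10 genome build were used. Their versions, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of near-identical genes, overlapping genes and antisense pairs could therefore be split or merged in ways the counts do not show. The table has 24116 genes named by Entrez gene number. Of these, 24061 were matched to a symbol in the RefSeq annotation of GRCm38.p6, the assembly that mm10 is built from, and 55 were not. The unmatched genes held 0.0334% to 0.0439% of the counts of a library. In total 5392 genes had no count in any library. Transposable elements and mitochondrial genes were not analysed here.

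Total counts were 19005131 and 18844246 in the wild-type libraries and 19056529 and 18872382 in the libraries labelled knockout. At these depths a count of 0 allows up to 3 counts, which is 0.157 to 0.159 CPM (scaled counts relative to the library total). Such limits cover counting error only, since PCR copies of a molecule are counted as separate reads. Groups and replicate numbers were taken from the sample titles. No label states that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

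Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 14194. Libraries were scaled by TMM. The quasi-likelihood F test compared knockout with wild type in a model of genotype alone, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are knockout minus wild type. Their standard error (SE) was taken as the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. A gene is called separated when both libraries labelled knockout lay on the same side of both wild-type libraries in CPM.

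A set of 39 gene lists was fixed before the data were examined, and covers chromatin factors, pluripotency, germline genes, other cell types, signalling, stress, metabolism and the neighbours of Kdm2a. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it.

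The rule for named genes, also fixed before the data were examined, took Kdm2a first. It then took the 10 largest changes per direction and the 5 lowest p-values among genes past the threshold with a mean of at least 5 CPM and separated libraries, and up to 3 members per list past the threshold. For a list with no such member it took the member with the highest mean CPM. No gene passed the threshold, so apart from Kdm2a and such members the genes named in the text were chosen after their values were seen.

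Tests were tried on simulated counts drawn from the means and library sizes of these 14194 genes, with 200 genes changed by known folds. The quasi-likelihood test called 0% of the genes changed 2-fold, 70% of those changed 4-fold, 74% of those changed 8-fold and 90% of those changed 16-fold, with 8 false calls. DESeq2 called 12%, 82%, 82% and 88% of them, with 38 false calls. When the 36 tested members of the germline list were lowered 2-fold in simulated counts, camera gave unadjusted p = 2.55e-18 with the preset correlation. With an estimated correlation camera gave unadjusted p = 0.0130 and adjusted p = 0.507. Camera with an estimated correlation and fry each called 0 of the 39 lists there, so a list that fails them may still be changed. In all these simulations each gene was drawn independently, so differences that many genes of a library share are missing. The shares of genes called and the p-values of the list may therefore not hold for the real libraries.

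Settings chosen before the data were examined were 3 other scalings, 2 other filters, ribosomal RNA genes left out before scaling, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, a block on the replicate number, a threshold of 0.01 and each library left out in turn. The germline list without near-identical copies and preset correlations of 0.05 and 0.1 were added after the data were seen. So was edgeR's glmTreat, which tested for changes beyond 2-fold between each of 3 libraries and the other 2, with knockout 2 left out, over the same 14194 genes.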

Results

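Gene expression was compared between wild-type embryonic stem cells of the mouse and cells labelled as a knockout of Kdm2a, a demethylase of histone H3 lysine 36, to ask how genes respond to the loss of this enzyme. The titles call these cells knockout, whereas the genotype label of the same samples calls Kdm2a knocked down. Each group had 2 libraries. Total counts lay between 18844246 and 19056529, so the groups did not differ in depth.

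Kdm2a RNA was not lower in the libraries labelled knockout. Kdm2a (Entrez gene 225876, GRCm38.p6 chromosome 19, 4316144 to 4398721) had 2899 and 3554 counts in the wild-type libraries against 3710 and 4753 in the libraries labelled knockout. Its mean was 168 ± 23.2 CPM (SD, n = 2) in wild type and 228 ± 47.7 CPM (SD, n = 2) in the others. The log2 fold change was 0.44 (SE 0.24), which did not pass the edgeR quasi-likelihood test (adjusted p = 1.00). The RNA level of the target thus neither bears out nor contradicts the knockout label, since reads over the whole gene do not show whether an allele makes protein. Every direction given here rests on the labels alone.

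The library labelled knockout 1 resembled both wild-type libraries more than it resembled knockout 2. Over the tested genes, the library labelled knockout 1 correlated with wild type 1 at r = 0.984 and with wild type 2 at r = 0.978, but with knockout 2 at r = 0.952. The wild-type libraries correlated at r = 0.968, and knockout 2 correlated with wild type 1 at r = 0.938, the lowest of the pairs, and with wild type 2 at r = 0.959. These are correlations across genes, which are not independent replicates. Among 7707 genes with a mean of at least 20 CPM, knockout 1 lay between the wild-type libraries for 51.7% and between wild type 1 and knockout 2 also for 51.7%, while wild type 2 lay between wild type 1 and knockout 2 for 46.3%, against 33.3% each if libraries were exchangeable. Chi-square values per degree of freedom, computed to look for a library deposited more than once, were 29.6 to 98.7 over the pairs, so no pair held the same counts.

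**Figure D1:**
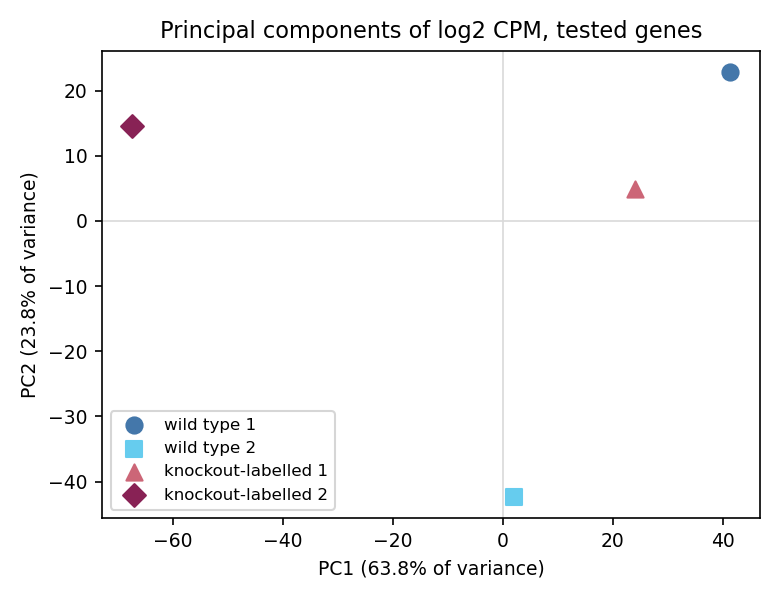
Principal components of log2 CPM over the 14194 tested genes, with the first component (63.8% of the variance) on the x axis and the second on the y axis, and 1 point per library. The library labelled knockout 2 lies at -67.4 on the first component and knockout 1 at 24.0, between wild type 2 at 2.01 and wild type 1 at 41.3.

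Mest, an imprinted gene expressed from the paternal allele, had the lowest p-value of all genes. It had 1336 and 1339 counts in wild type against 87 and 196 in the libraries labelled knockout, a log2 fold change of -3.18 (SE 0.44), with adjusted p = 1.00 by the quasi-likelihood test and 3.23e-09 by DESeq2. Tuba3a, a testis alpha-tubulin, followed at -1.55 (SE 0.27), with an adjusted p of 0.0280 by DESeq2. Sohlh2, a transcription factor of germ cell differentiation, was at -1.36 (SE 0.26), and Dazl, an RNA-binding protein of germ cells, at -1.71 (SE 0.36). On the other side, Ntn1, which encodes the guidance cue netrin-1, was at 1.46 (SE 0.38), Foxp4, a forkhead transcription factor, at 0.86 (SE 0.22), and Ccnd2, a D-type cyclin, at 1.42 (SE 0.41).

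No single gene passed the threshold. The edgeR quasi-likelihood test called 0 of 14194 genes at an adjusted p under 0.05, and 242 had an unadjusted p under 0.05 (126 higher, 116 lower in the libraries labelled knockout), where chance alone gives 709.7. DESeq2 called 2 genes, Mest and Tuba3a, the edgeR likelihood ratio test called 4, which added BB287469 and 1700013H16Rik, and limma-voom called 0. Separated genes numbered 3459, or 24.4%, below the 33.3% that chance gives. Without knockout 1 the quasi-likelihood test called 91 genes and without knockout 2 it called 8, with Mest the 1 gene in both sets.

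**Figure D2:**
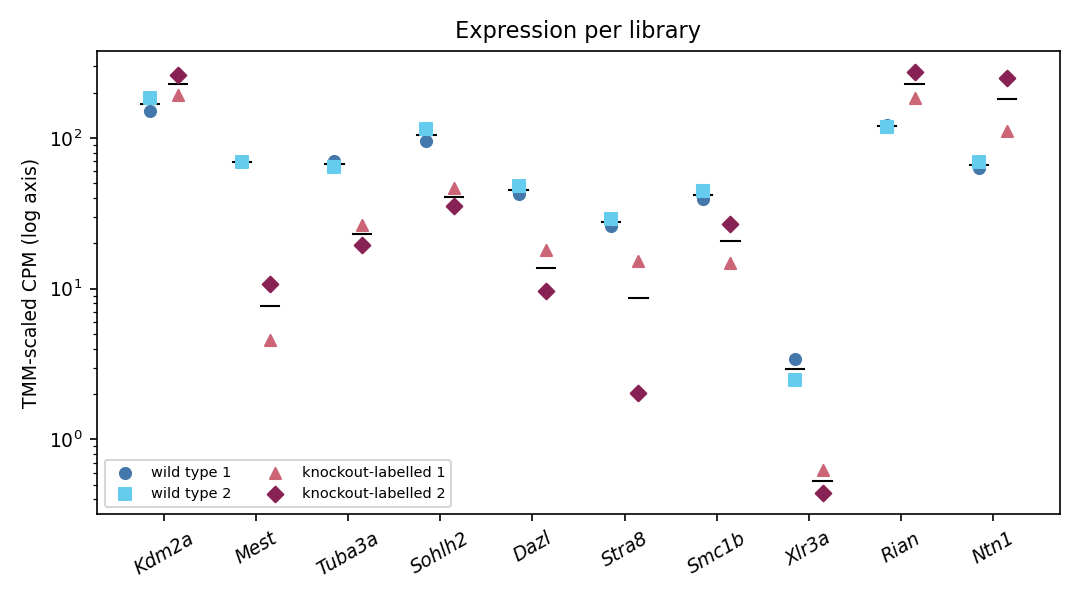
TMM-scaled CPM of 10 genes in each library, on a log axis, with 1 point per library and a bar at the mean of each group of 2. Mest is at 69.8 and 69.4 CPM in wild type and at 4.55 and 10.8 CPM in the libraries labelled knockout, and Kdm2a is not lower in the latter.

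Germline and meiosis genes were lower as a group in the libraries labelled knockout. Of 36 members tested, 32 had a negative fold change, 19 were separated and lower and 0 were separated and higher, with a median log2 fold change of -0.62. Besides Tuba3a, Sohlh2 and Dazl, Xlr3a, an X-linked gene with near-identical copies, was at -2.45 (SE 0.62), Smc1b, the meiotic cohesin subunit, at -1.01 (SE 0.35), and Stra8, which brings germ cells into meiosis, at -1.67 (SE 0.78). The most abundant member, Hsf2bp, was at -0.07, and at 0.15 and 0.03 without wild type 1 and without knockout 1. The library medians were -0.42 in knockout 1 and -1.12 in knockout 2, relative to the wild-type mean. Camera with the preset correlation gave adjusted p = 2.05e-14, and adjusted p = 0.853 with an estimated correlation (unadjusted p = 0.0833). Adjusted over the list alone, 4 members passed, all lower (Tuba3a, Sohlh2, Dazl and Xlr3a), against 0 over all genes tested. Tuba3a and Tuba3b share most of their sequence, so their separate counts are uncertain.

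A further 3 lists were lower by camera with the preset correlation. In the epithelial junction and adhesion list, 18 of 26 members had a negative fold change (adjusted p = 5.34e-05, and adjusted p = 0.853 with an estimated correlation). Cdh1, which encodes E-cadherin and was its most abundant member, averaged 839 ± 42.2 CPM in wild type and 576 ± 217 CPM in the libraries labelled knockout (SD, n = 2 each). Epcam, an epithelial adhesion protein, was at -0.76 (SE 0.27). In the cholesterol synthesis list 22 of 25 members were negative, with a median of -0.26 (adjusted p = 0.000144, and adjusted p = 0.853 with an estimated correlation), and Insig1, a sterol-regulated brake on this pathway, was at -0.85 (SE 0.32). In the 2-cell-like list, 21 of 26 members were negative (adjusted p = 0.000209, and adjusted p = 0.853 with an estimated correlation), but its median was 0.17 in knockout 1 and -1.53 in knockout 2, and its call ended and its direction turned without knockout 2 (adjusted p = 0.274). Without wild type 2 its adjusted p was 0.395. Cholesterol synthesis lost its call without knockout 2 (adjusted p = 0.157) and without wild type 1 (adjusted p = 0.0571).

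The other 5 lists past the threshold were higher, with small medians. Among the H3K36 and KDM2-family demethylases, 6 of 8 members were positive, Kdm2a included, with a median of 0.30 (adjusted p = 0.0296, and adjusted p = 0.853 with an estimated correlation). Kdm2b, the paralog of Kdm2a, was at 0.54 (SE 0.28), and the list median was 0.12 in knockout 1 and 0.61 in knockout 2. Cytosolic ribosomal proteins had 50 of 71 positive members and a median of 0.07 (adjusted p = 0.00857, and adjusted p = 0.955 with an estimated correlation), and their direction turned without wild type 2 (adjusted p = 0.0153). Their medians of 0.08 in knockout 1 and 0.11 in knockout 2 lay between those of wild type 1 (0.23) and wild type 2 (-0.23), which differed by -0.46. RNA polymerase I and ribosome biogenesis genes had 40 of 50 positive members (adjusted p = 0.0196, and adjusted p = 0.853 with an estimated correlation). Glycolysis and hypoxia genes had 27 of 35 positive members (adjusted p = 0.0258, and adjusted p = 0.853 with an estimated correlation), while Gapdh, a glycolytic enzyme with many processed copies, was at -1.60 (SE 0.37) and Egln3, a prolyl hydroxylase, at 0.92 (SE 0.28). That direction turned without wild type 2 and without knockout 2 (adjusted p = 0.613 and 0.997). Heat shock genes had 11 of 16 positive members (adjusted p = 0.0296, and adjusted p = 0.853 with an estimated correlation). Calls also ended for the demethylases without wild type 2 and without knockout 2 (adjusted p = 0.0655 and 0.540), for ribosomal proteins without knockout 1 and without knockout 2 (0.233 and 0.0874), and for RNA polymerase I genes without wild type 1 and without knockout 1 (0.995 and 0.487). The heat shock call ended without wild type 1, knockout 1 or knockout 2 (0.126, 0.238 and 0.120).

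**Figure D3:**
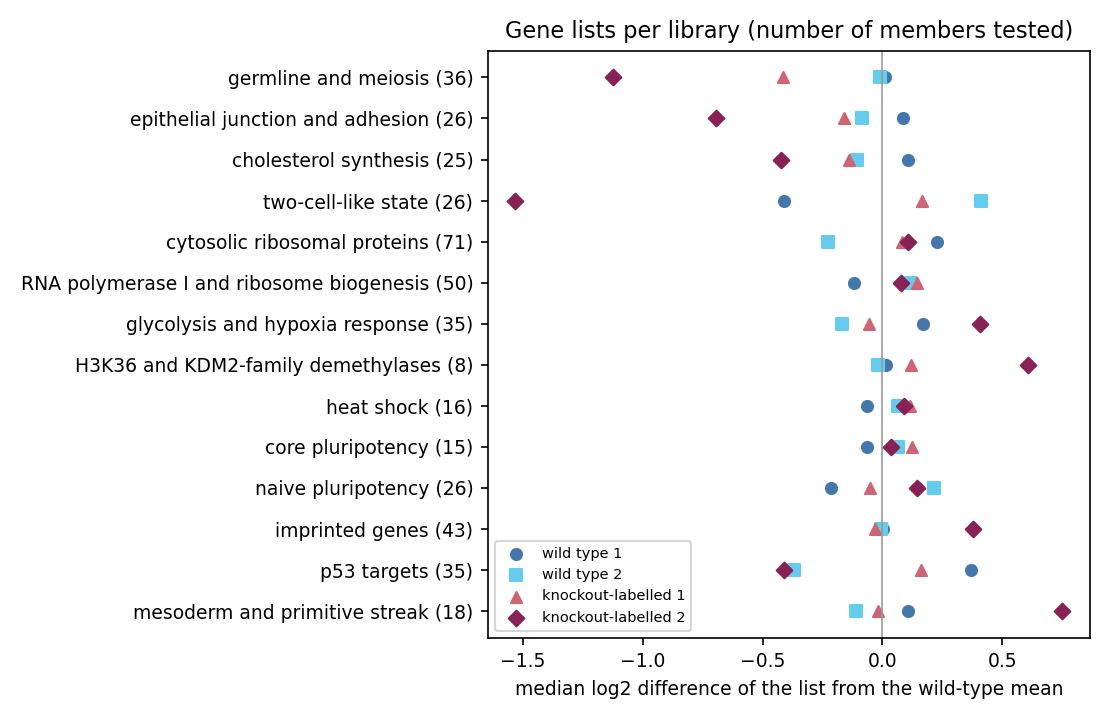
Median log2 difference of 14 gene lists from the wild-type mean (x axis), with 1 point per library and the number of members tested in brackets. The wild-type points mirror each other by construction, since the mean is that of these same libraries. The germline list lies at -0.42 and -1.12 in the libraries labelled knockout and at 0.01 and -0.01 in wild type, whereas the 2-cell-like list lies at 0.17 in knockout 1 and at -1.53 in knockout 2.

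Pluripotency genes did not pass as groups with all 4 libraries. The median log2 fold change was 0.04 over 15 core members, 0.03 over 26 naive members and 0.06 over 21 formative and primed members, with adjusted p = 0.206, 0.823 and 0.729 by camera with the preset correlation. The naive list passed as lower without wild type 1 (adjusted p = 0.0237) and as higher without wild type 2 (adjusted p = 0.0135), and the core list passed as higher without wild type 2 (adjusted p = 0.00704). These calls were lost with an estimated correlation, at adjusted p = 0.871 without wild type 1 and adjusted p = 0.686 without wild type 2. Pou5f1, which encodes OCT4, averaged 939 ± 180 CPM in wild type and 998 ± 107 CPM in the libraries labelled knockout (SD, n = 2 each). Esrrb, the most abundant naive member and an orphan nuclear receptor, averaged 991 ± 47.6 and 1123 ± 22.1 CPM (SD, n = 2 each). Markers of mesoderm, endoderm and fibroblasts did not pass either with all 4 libraries. Mesoderm and primitive streak genes had a median of 0.38 (adjusted p = 0.0956), which was -0.02 in knockout 1 and 0.75 in knockout 2, endoderm genes 0.13 (adjusted p = 0.377), and fibroblast and matrix genes -0.11 (adjusted p = 0.136). Mesoderm genes passed as higher without wild type 1 (adjusted p = 0.0491), without knockout 1 (0.0108) and with scaling by library totals only (0.0466), endoderm genes as higher without wild type 1 (0.0420) and without knockout 1 (0.0483), and fibroblast genes as lower without knockout 2 (0.00623). These calls were lost as well, at adjusted p = 0.871 without wild type 1, 0.876 without knockout 1, 0.8505 with library totals and 0.937 without knockout 2 with an estimated correlation. For 3 lists the median, mean and test differed in sign: trophoblast (median 0.17, mean 0.03, test lower), NF-kB targets (0.07, -0.04, lower) and ATF4 targets (-0.000545, 0.07, higher), none of which passed with all 4 libraries (the lowest adjusted p was 0.723), while ATF4 targets passed as higher without wild type 1 (adjusted p = 0.00327, and adjusted p = 0.871 with an estimated correlation). The 38 tested neighbours of Kdm2a on chromosome 19 had a median of -0.05 (adjusted p = 0.719).

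Imprinted genes went both ways. Of 43 tested, 30 were positive and 13 negative, and the list did not pass (adjusted p = 0.212). Adjusted over the list alone, 1 member passed, Mest, against 0 over all genes tested. H19, a maternally expressed RNA, had 235 and 84 counts in wild type against 8 and 46 in the libraries labelled knockout, and Rian and Meg3, maternally expressed RNAs of a shared domain on chromosome 12, were at 0.93 (SE 0.26) and 0.76 (SE 0.27). Among 8 Y-linked and X inactivation genes, Kdm5d, a Y-linked demethylase, had 38 and 60 counts against 6 and 14, and neither it (adjusted p = 0.128 over the list alone) nor the list (adjusted p = 0.840) passed. No member of the lists other than germline and imprinted genes passed adjusted over the list alone.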

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

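Tests chosen only after the result was seen were those of single libraries, of 2-cell-like cells and of near-identical copies for the germline genes (for the copies the outcome was predicted beforehand), and all those on the likeness of the libraries. Germline and meiosis genes had negative medians in both libraries labelled knockout. This difference passed camera with the preset correlation but not with an estimated correlation (adjusted p = 0.853) or fry (adjusted p = 0.967). Both of the latter tests also missed a simulated 2-fold lowering of this list, so failing them cannot decide whether it changed. Knockout 2 was not alone in having a negative median, since the median was -0.42 in knockout 1, where the wild-type libraries differed by -0.02. The difference of knockout 2 minus knockout 1 was -0.87, so the -0.42 lies within the spread seen between libraries of 1 label. Reads shared between near-identical copies do not account for the germline difference, as the median stayed at -0.54 over the 31 members outside such families. For knockout 1, fewer 2-cell-like cells are argued against by its 2-cell-like median of 0.17. The wild-type libraries also differed by 0.82 in that list without such a germline difference. In knockout 2 the 2-cell-like median was -1.53, so fewer such cells stay open there. A response to genotype and a property of the single clone stay open, and the design cannot separate them.

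The library labelled knockout 1 lay nearer to both wild-type libraries than to knockout 2. Whether knockout 1 may hold mainly wild-type RNA stays open. Single genes were far below wild type there, but they were picked after their values were seen and so cannot decide it. Mest stood at 6.53% of the wild-type mean (95% exact Poisson interval 5.23 to 8.05, counting error only). Nnat (370 and 383 counts in wild type, 27 in knockout 1), Efhc2 (180 and 200, against 18), BB287469 (37 and 54, against 1) and 1700013H16Rik (34 and 40, against 1) were also low. Of these, Nnat was not low in knockout 2 (463 counts). Sets of genes did not decide the question either. Of 236 genes at no more than 25% in knockout 2, 3 (1.27%) were low in knockout 1. Low meant below 0.5 of the lower wild-type level by more than a negative binomial spread. With wild type 1 and wild type 2 in its place 1 of 204 and 0 of 282 were low, which Fisher's exact test (one-sided) did not separate (p = 0.368 and 0.0939). The test with edgeR's glmTreat, run without knockout 2, could not decide it. Each of its fits set 1 library against 2, and Fisher's exact test cannot separate libraries on so few calls. Gain or loss of a whole chromosome in all cells of knockout 2 is argued against for chromosomes 1 to 19 and X. The largest median was 0.17 (X), where 3 copies against 2 give 0.58. A change in only part of the cells would give a smaller median and stays open, and Y was not tested. A difference shared by libraries of the same number stays undecided. Split by number, edgeR's quasi-likelihood test gave 1995 genes at an unadjusted p under 0.05, against 242 by genotype and 285 in the crossed split. A shared difference predicts that larger count, but 0 genes passed after adjustment in each split. Wild type 2 correlated better with knockout 1 (r = 0.978) than with knockout 2 (r = 0.959). Knockout 2 correlated less with every library than the others did with each other, so this cannot count against a shared number. Wild type 1 and knockout 1 correlated best of all pairs (r = 0.984), and the best partner of knockout 2 was wild type 2.

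Kdm2a RNA was not lower in the libraries labelled knockout. Scaling does not account for this, as the lowest log2 fold change over the 4 scalings was 0.39. An allele that stops the protein and leaves the RNA could give the observed 0.44, but so could cells that keep the gene, and counts over a whole gene cannot be told apart between these.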

How the results depend on the processing

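Preset correlations of 0.05 and 0.1 and the germline list without near-identical copies were chosen after the result was seen, and the other settings were planned. The count of 0 genes held under 3 other scalings, 2 other filters, limma-voom and the threshold of 0.01. DESeq2 called 2 genes and the edgeR likelihood ratio test 4, all lower and at least 2-fold. With each library left out in turn, genes called ranged from 0 to 91, higher from 0 to 75, lower from 0 to 16, and at least 2-fold from 0 to 91, where the lone library of a group is assumed to vary like the other group. Leaving out ribosomal RNA genes changed none of the values, so it tests nothing here. Kdm2a kept a positive log2 fold change in every setting, from 0.21 without knockout 2 to 0.64 without knockout 1. Among genes given with a fold change or group means, Hsf2bp turned to 0.15 without wild type 1 and 0.03 without knockout 1 (lowest -0.25) and Pou5f1 to -0.0874 without wild type 2 and -0.03 without knockout 1 (highest 0.30), and no other turned; genes described for single libraries only, such as Grb10, Impact and Nnat, were not run.

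The number of lists past the threshold ranged from 7 to 14 with a library left out, and was 0 with an estimated correlation, 0 with fry, 4 at a preset correlation of 0.05 and 1 at 0.1. The 1 was the germline list, which passed with each library left out (adjusted p from 7.94e-14 to 9.95e-09), without near-identical copies (3.26e-10) and at 0.1 (0.000341), but not with an estimated correlation (0.853) or fry (0.967). Directions turned for ribosomal proteins (0.0153 without wild type 2, range 7.85e-23 to 0.233), glycolysis (0.613 without wild type 2 and 0.997 without knockout 2, lowest 3.19e-08) and the 2-cell-like list (0.274 without knockout 2, range 1.15e-08 to 0.395). The cause was not tested. Of lists not past the threshold with all libraries, p53 targets passed whichever library was left out, but never with an estimated correlation. The direction was higher without wild type 1 or knockout 2 and lower without wild type 2 or knockout 1. The median log2 difference of this list was -0.74 for wild type 2 minus wild type 1 and -0.57 for knockout 2 minus knockout 1. Libraries numbered 2 were thus lower in both groups. Leaving out 1 library unbalances these numbers between the groups, so the p53 calls cannot be read as a response to genotype.

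With the replicate number as a block, edgeR called 0 genes (735 at an unadjusted p under 0.05) and 8 lists passed: glycolysis (0.0725) and heat shock (0.0521) were lost and p53 targets gained as lower (0.0440, and adjusted p = 0.837 with an estimated correlation). Same-number libraries deviated together (r = 0.347 across genes), but 2 pairs without a label do not establish pairing. The quasi-likelihood test called 0% of genes simulated with a 2-fold change, the likelihood ratio test 8% and DESeq2 12%. These genes were drawn independently, so the shares may not hold for the real libraries.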

Other observations

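The tests of lysosomal genes and of imprinted genes were chosen after single genes of each kind had been seen, with their outcomes predicted before the values were computed, and the lysosomal list leaves out the genes that drew attention to it. The test of imprinted genes without those already seen was chosen after the result was seen. The library labelled knockout 2 stood apart in a set of genes chosen after their values were seen. Txnip, which binds thioredoxin and restrains glucose uptake, had 112 counts there against 22348, 3461 and 8662 in wild type 1, wild type 2 and knockout 1, and its relative Arrdc4 had 143 against 1469, 927 and 1165. Rragd, a GTPase that recruits mTORC1 to lysosomes, had 1806 against 406, 487 and 382. Gpnmb, a lysosomal glycoprotein, had 187 against 26, 19 and 18, and Ctsl, a lysosomal protease, 5795 against 2205, 1868 and 1788. These are values of 1 library and have no replicate check.

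Lysosomal targets of the transcription factors TFEB and TFE3 may be more active in that library. Over 63 such genes the median log2 difference of knockout 2 from the mean of the other libraries was 0.68, above the upper bound (0.16) of the central 95% of 10000 random lists matched on expression, and 47 of the 63 were highest there. The median of knockout 1 against the wild-type mean was -0.10, below all 10000 random lists, so the libraries labelled knockout differed in opposite directions. The same list also differed between the wild-type libraries, at -0.41 for wild type 2 minus wild type 1, below all 10000 random lists. Each of these comparisons thus fell outside the random lists, so passing their bound is not particular to knockout 2. A culture difference and a response to genotype cannot be separated in 1 library.

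Whether imprinted genes vary between these libraries more than other genes do stays open. The median SD of log2 CPM over the 4 libraries was 0.57 for all 43 imprinted genes tested, above the upper bound (0.41) of the central 95% of matched random lists, but these include the genes that drew attention to the list. Without 9 such genes the median of the other 34 was 0.40, under the upper bound of 0.44, in a list that then lacks members picked for their differences. Single libraries stood out in different genes: Nnat had 27 counts in knockout 1 against 370, 383 and 463 in wild type 1, wild type 2 and knockout 2, whereas Grb10 had 199 in knockout 2 against 1582, 1351 and 3896 in wild type 1, wild type 2 and knockout 1. Impact had 8792 in knockout 2 against 2042, 2913 and 1184. In a count added after these values were known, 3 of 8349 genes with at least 5 CPM in both wild-type libraries, which lay within 1.5 times of each other, were at no more than 25% of the lower of them in knockout 1 (Efhc2, Mest and Nnat), and 29 were in knockout 2.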
